A study of Aspergillus oryzae with 8 samples.

How the data were processed

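Polyadenylated RNA of Aspergillus oryzae RIB40 was sequenced in 8 libraries, 2 for each of 4 conditions: solid and liquid culture, each untreated and with 20 mmol/L DTT. Per the labels' protocols, the medium held 2.0% glucose at pH 5.5. Control mycelium grew for 40 h at 30 °C, on cellophane over agar or in 30 mL of medium shaken at 200 rpm. The labels of the treated libraries give neither growth time nor temperature. For treatment, DTT was added to the liquid culture, while on agar the cellophane with the mycelium was moved onto filter paper soaked with 20 mL of medium holding DTT. Per the labels, messenger RNA was selected on oligo-dT beads, cDNA was primed with random primers, and 44 bp were read from both ends of fragments of 500 bp (replicate 1 of every condition) or 200 bp (replicate 2). The labels do not mention strand, so reads of a gene and of an antisense partner cannot be told apart.

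Per the file headers, the deposited files give for each gene the number of mapped reads, used here as raw counts, and the fraction of the gene covered by reads. The aligner, genome build, annotation, and treatment of reads that map to several genes are not given in the sources used here. No normalized unit was used, so alternatives planned for one (limma on normalized values, other pseudocounts and filters on values) did not apply. The deposited coverage fraction was used to examine genes listed with coverage and 0 reads and to recover coding lengths from the fractions' denominators. These lengths, which may be only divisors of the true ones, were multiples of 3 for 98.8% of protein-coding genes, and 3113 were under 700 bp. The libraries held 6176818 and 8216798 reads (solid control, replicates 1 and 2), 5880753 and 7837291 (liquid control), 7314033 and 8912897 (solid DTT) and 6067143 and 8750217 (liquid DTT). The share on 3 rRNA genes was 27.1% and 8.2%, 25.2% and 15.7%, 37.6% and 17.1%, and 17.7% and 20.6% in the same order. Median coverage of listed genes was 68.1% to 77.3% in replicate 1 and 94.9% to 95.5% in replicate 2. At these depths 3 reads correspond to 0.34 to 0.51 CPM, and genes identical in sequence to another may be undercounted.

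All 11880 locus tags of the files were matched to the RefSeq gene table of assembly ASM18445v3, which was used for names, gene types and the order of genes only, since the build of the files is not known. It gives symbols to 714 of 12347 genes, and other genes are printed by locus tag.

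Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10), which left 9438, and scaled by TMM (factors 0.73 to 1.25). All 8 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with 1 coefficient per condition and 4 residual degrees of freedom. The p-values were Benjamini-Hochberg adjusted over genes within each comparison and called under 0.05. The comparisons were DTT against control in each culture, solid against liquid culture without and with DTT, and the difference of the 2 DTT effects. Each SE is the log2 fold change divided by the root of the F statistic. CPM are scaled by TMM, and log2 CPM use a prior count of 2. The common biological coefficient of variation was 0.47, and 0.36 with the block.

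Replicate numbers coincide with the insert size given in the labels, so they pair the libraries by insert size. The labels name no library batch. The differences between replicate 1 and replicate 2 correlated between conditions at 0.24 to 0.51. The fit with insert size as a block (3 residual degrees of freedom) is printed beside a result where it changes a call or moves a count by over 1.5 times. Counts of the 2 libraries of a condition differed by more than sampling noise (chi-square per degree of freedom 179.3 to 265.3), so they were not 1 library deposited 2 times, although they may be 2 preparations of the same RNA.

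A fold against a condition with 0 reads is a bound against a floor of 3 reads over the 2 libraries. With 1 to 3 reads the ratio is given with its exact 95% binomial interval, which covers counting error only, as does the floor. Genes named were, per comparison, the 8 with the largest rise and the 8 with the largest fall (5 and 5 for the difference) among called genes with a symbol, the same direction in all 4 pairs of libraries (for the difference, in both replicate numbers) and at least 20 CPM in the higher condition. Up to 4 members of each gene list described and 16 genes followed throughout were named too. The design, tests, names of the gene lists with their search words and these rules were set before the data were examined. The values of clxA in solid culture, of fmpA, nrps1 and fma-PKS between the cultures and of 4 genes called with the block for the difference were singled out after they were seen, as was the split of the secondary metabolism list into gli and other genes.

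The 32 gene lists were to be filled by searching gene descriptions, but the reference holds symbols only, so members were assigned by hand from symbols and listed locus tags. This was done before any fold change was computed, although raw counts of some listed genes had been seen. 2 further lists, retention signals at protein ends and fermentation, could not be filled and were not tested. Members are named for lists with a call, a called member or, under DTT, for the lists of ER folding, ER-associated degradation, the proteasome and chaperones, a limit set after values had been seen. The 21 lists with at least 5 tested genes were tested with limma 3.58.1's camera on log2 CPM (preset correlation 0.01), Benjamini-Hochberg adjusted over 105 tests, beside camera with an estimated correlation and fry. A list of zinc uptake genes was added after values had been seen.

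Alternatives were median-ratio (RLE) and upper-quartile scaling, no filter and a filter of 50 reads in 2 libraries, the block, the block on genes of 700 bp or more, only the 4 libraries compared, each library left out in turn, a threshold of 0.01, a test against a fold change of 1.5 (glmTreat), DESeq2 1.42.0 and, added after seeing the data, rRNA and tRNA genes left out. A lone library left in a condition is assumed to vary like the other conditions.

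The tests were tried on counts simulated from the means, library sizes and spread of these libraries for 9438 genes, of which 100 changed 2-fold and 100 changed 4-fold. Fewer genes changed there than were called in each comparison of the real data but the difference of effects. Adjustment is stricter where fewer genes change, so the shares below are not the recovery in the real data. edgeR's test recovered 0 of 100 genes changed 2-fold in each comparison. Of those changed 4-fold it recovered 11 (DTT, solid), 6 (DTT, liquid), 5 (cultures, control), 10 (cultures, DTT) and 2 (difference of effects), with 0 false calls in each. DESeq2 recovered 29, 32, 24, 30 and 9 of them, with 17, 15, 12, 6 and 6 false calls. Camera gave p of 3.4e-08, 5.68e-08, 1.11e-08, 1.22e-10 and 0.0924 to a list of 20 genes raised 2-fold, so the list was missed for the difference of effects, and p under 0.05 to 2, 4, 5, 7 and 8 of 200 unchanged lists. The simulated genes were drawn independently of each other, and only the preset correlation was tried. These values therefore do not show how often camera calls unchanged lists of genes that vary together.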

Results

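The libraries held RNA of Aspergillus oryzae RIB40, a filamentous fungus used in food fermentation, grown in 4 conditions with 2 libraries each. Mycelium was grown either on cellophane over agar (solid culture) or in shaken flasks (liquid culture) and was left untreated or given 20 mmol/L dithiothreitol (DTT), a reducing agent that breaks disulfide bonds and so disturbs protein folding in the endoplasmic reticulum (ER). Each library held between 5880753 and 8912897 reads assigned to genes, and 9438 of 11880 listed genes had enough reads to be tested. Between 8.2% and 37.6% of these reads fell on rRNA genes. Nothing in the labels says that the 2 libraries of a condition come from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels give no DTT exposure time, and on agar the treated mycelium was also moved to soaked filter paper, a step the labels do not describe for the controls.

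Libraries of the same condition were the most alike, with Pearson correlations of log2 CPM (reads scaled to library size) across genes between 0.90 and 0.93. Libraries that shared only the replicate number, which is also the library insert size, correlated at 0.65 to 0.86, and pairs that shared neither at 0.61 to 0.85. The first principal component held 48.2% of the variance and separated DTT from control, the second (22.1%) separated solid from liquid culture, and the third (11.4%) separated the 2 insert sizes. Below, fold changes are log2 values ± SE from edgeR's fit, CPM are means ± SD (n = 2 libraries per condition), and a gene rose, fell or was higher or lower only where its adjusted p was under 0.05.

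**Figure D1:**
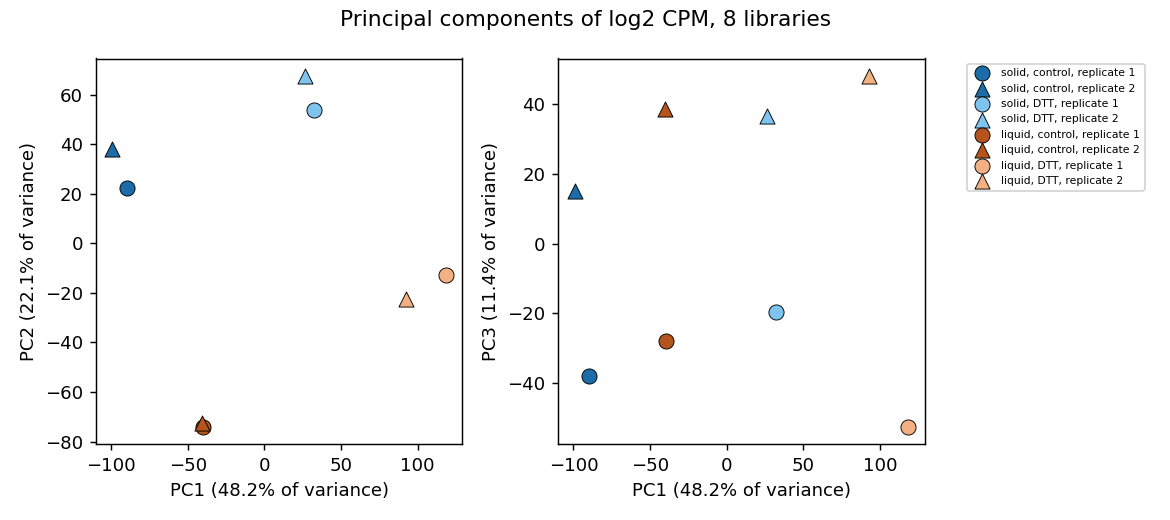
Principal components of log2 CPM over the 9438 tested genes, with each point 1 library, colour for condition and marker shape for replicate number. The left panel plots the first (48.2% of variance) against the second component (22.1%), and the right panel the first against the third (11.4%), on which replicate 1 libraries (500 bp inserts) lie below 0 and replicate 2 libraries (200 bp inserts) above 0.

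The first question, posed by the series title, was what ER stress changed in mycelium on a solid surface. Under DTT, transcripts of bipA (AO090003000257), the Hsp70 chaperone of the ER lumen, rose from 765 ± 51.8 to 8880 ± 611 CPM (n = 2 each). Its log2 fold change was 3.54 ± 0.78. Genes of ER-associated degradation rose with it, derA (AO090701000076) by 2.88 ± 0.59 and the ubiquitin ligase gene hrdA (AO090005000658) by 2.51 ± 0.46, as did the signal peptidase gene sec11 (AO090012000838) (1.87 ± 0.37). The thioredoxin reductase gene trr1 (AO090009000289) rose from 229 ± 41.9 to 3210 ± 291 CPM. The trehalase gene treA (AO090120000052) (-4.55 ± 0.58), siderophore uptake genes, genes of leucine and valine synthesis and a gene of sulfur assimilation fell. In all, 878 of 9438 genes changed, 459 up and 419 down, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 878 moved the same way in each of the 4 pairs of a treated and a control library, and the smallest log2 change among them was 1.37. With 2 libraries per condition a call nearly requires this agreement, so it is no added support.

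Of the 3 ER folding genes in the list, bipA rose in solid culture (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0282). When adjusted over the list alone, 3 were called, and with the insert size as a block 3. The protein disulfide isomerase gene pdiA (AO090001000733) stood at 2.17 ± 0.65 and the calnexin gene clxA (AO090009000313) at 2.48 ± 0.73. Their adjusted p were 0.0682 and 0.0656 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.0199 and 0.0188 with the block. The transcription factor gene hacA (AO090124000074), whose mRNA is spliced in the unfolded protein response, stood at 0.76 ± 0.48 and was not called. In the ER-associated degradation list 2 of 5 genes rose (2 adjusted over the list alone; camera adjusted p = 0.104). None of 16 proteasome genes was called (0 adjusted over the list alone), with rpt1 (AO090020000414) at 0.81 ± 0.45 and pre1 (AO090023000824) at 0.33 ± 0.44. None of 10 cytosolic and mitochondrial chaperone genes was called either (0 adjusted over the list alone, 1 with the block), with hsp70 (AO090012000995) at -0.37 ± 0.85 and hsp90 (AO090102000620) at 0.01 ± 0.72. In the thiol and peroxide defence list trr1 alone of 9 genes rose, 5 were called when adjusted over the list alone (3 up, 2 down) and 5 with the block. The catalase gene cat1 (AO090120000068) stood at 2.45 ± 0.67. Its adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0526, and 0.0208 with the block.

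Among called genes with a symbol and at least 20 CPM in the higher condition, the largest rises were those of the transporter genes atrF (AO090701000115) (5.44 ± 0.65) and mdr1 (AO090009000651) (3.49 ± 0.71), fdh (AO090701000046) (4.90 ± 0.90), trr1, bipA, rad7 (AO090026000832) (3.09 ± 0.52), hxB (AO090023000633) (3.0 ± 0.59) and derA. Under the same limit the largest falls were those of AfusinC (AO090001000098) (-6.40 ± 1.69), the siderophore esterase gene sidJ (AO090103000170) (-4.72 ± 0.96), treA, the zinc transporter gene zrfC (AO090005000940) (-4.55 ± 0.88), mfsA (AO090038000167) (-4.53 ± 0.59), leu2A (AO090005001122) (-4.51 ± 0.64), aspf2 (AO090005000939) (-4.30 ± 1.02) and the siderophore transporter gene mirB (AO090701000329) (-4.16 ± 0.91). In AfusinC the control libraries themselves ranged widely (30.8 ± 35.5 CPM), as did the treated ones in fdh (385 ± 378 CPM).

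5 lists were lower under DTT in solid culture by camera with a preset correlation, and for none of them was the call kept with an estimated correlation. Iron uptake fell in 5 of 10 genes (8 adjusted over the list alone, 9 with the block; camera adjusted p = 0.000155, adjusted p = 0.734 with an estimated correlation), with a median of -3.62. In amino acid synthesis 5 of 18 genes fell (5 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.81 with an estimated correlation), among them leu2A of leucine and ilv3 (AO090023000127) of branched-chain synthesis (-3.36 ± 0.60). In sterol and isoprenoid synthesis erg8 (AO090010000471) rose (1.76 ± 0.43) and 4 of 17 genes fell, such as erg24B (AO090009000362) (-2.74 ± 0.55) and idi1 (AO090023000500) (-2.54 ± 0.42). Adjusted over the list alone, 1 sterol gene rose and 9 fell, and 8 fell with the block (camera adjusted p = 0.0141, adjusted p = 0.789 with an estimated correlation). Of 28 ribosome assembly genes only rex4 (AO090001000667) fell (-2.01 ± 0.50; 0 adjusted over the list alone, 2 with the block), but all 28 had values below 0 (camera adjusted p = 0.00344, adjusted p = 0.81 with an estimated correlation). None of 5 cytosolic ribosomal protein genes was called (3 adjusted over the list alone, 1 with the block), with rps1 (AO090009000715) at -1.76 ± 0.79 and rpL3 (AO090026000458) at -1.98 ± 0.75 (camera adjusted p = 0.0257, adjusted p = 0.795 with an estimated correlation). Without solid control replicate 2, camera adjusted p was 0.0844 for amino acid synthesis, 0.0989 for sterols, 0.275 for ribosome assembly and 0.0681 for ribosomal proteins.

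In the list of sulfur assimilation and methionine (sulfur assimilation list below) the ATP sulfurylase gene sC (AO090020000349) (-3.88 ± 0.58) and mde1 (AO090009000312) (-1.98 ± 0.49) fell among 4 genes (3 adjusted over the list alone). In protein glycosylation the mannosyltransferase gene och3 (AO090010000615) rose (3.28 ± 0.50) and the mannose phosphate isomerase gene pmi1 (AO090012000554) fell (-2.15 ± 0.46) among 17 genes (2 adjusted over the list alone; 3 with the block). The autophagy kinase gene atg1 (AO090023000647) rose (2.73 ± 0.47), as 1 of 10 genes of autophagy and vacuole (1 adjusted over the list alone; 2 with the block). Single falls were seen in the lists of peptidases (dppIV (AO090023000602), -3.52 ± 0.65, of 8 genes; 3 adjusted over the list alone and 3 with the block), glycolysis (glucokinase gene glkA (AO090120000109), -2.27 ± 0.50, of 4; 1 adjusted over the list alone), the fungal cell wall (agm1 (AO090001000429), -2.10 ± 0.45, of 29; 1 adjusted over the list alone) and spore formation (flbD (AO090005000765), -2.29 ± 0.59, of 10; 1 adjusted over the list alone, 2 with the block). In the kojic acid cluster AO090113000138 (2.81 ± 0.61) and AO090113000137 (1.62 ± 0.39), to which the reference gives no symbol, rose. AO090113000136 stood at 0.08 ± 0.46 (2 of 3 genes; 2 adjusted over the list alone). No gene was called in the lists of starch hydrolysis (5 genes), plant wall hydrolases (12), vesicle transport (10), the tricarboxylic acid cycle (4), the respiratory chain (8), the mitochondrial ribosome (3), nitrite reductase (1), secondary metabolism (15), cyclopiazonic acid (2), aflatoxin homologues (10), hexose transport (1), oligopeptide transport (4) and cell division (13). Of these, adjusted over the list alone, 1 respiratory gene fell and 0 genes were called in the others. With the block cell division was lower (camera adjusted p = 0.0357, adjusted p = 0.909 with an estimated correlation, and 0.0632 without the block). 3 of its genes fell with the block, as did 2 respiratory genes. Also with the block 2 plant wall hydrolases rose, and 1 secondary metabolism gene rose and 3 fell.

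The starch hydrolysis list was tested without AO090003001210, which no file listed, and without AO090023000944 and AO090120000196. The last 2 had 0 to 8 reads per library at 98.3% to 100% coverage, so their level is not known. Among genes followed in every comparison, those of the starch hydrolysis list, AO090010000746 (-0.27 ± 0.71), AO090003000321 (-2.24 ± 1.07) and AO090003001208 (-0.76 ± 0.46), were not called in solid culture. The same held for the glyceraldehyde phosphate dehydrogenase gene gpdA (AO090003001322) (-0.57 ± 0.82), aspf22 (AO090003000055) (-0.92 ± 0.85), AO090120000080 (-0.94 ± 0.89), AO090020000588 of the cell wall list (-0.56 ± 0.55) and the peptidase list's AO090003001036 (-2.16 ± 0.74) and AO090120000474 (-1.46 ± 0.75). The block raised the count from 878 to 1897, which held all 878. Leaving out 1 library gave 6 genes (2 up, 4 down) without solid control replicate 1, 23 (5 up, 18 down) without solid control replicate 2, 167 (137 up, 30 down) without solid DTT replicate 1 and 85 (72 up, 13 down) without solid DTT replicate 2. Of the 34 calls named here 0, 1, 6 and 4 were then kept. The adjusted p of bipA was then 0.151, 0.194, 0.0834 and 0.0967 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at log2 fold changes of 3.46 to 3.63.

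**Figure D2:**
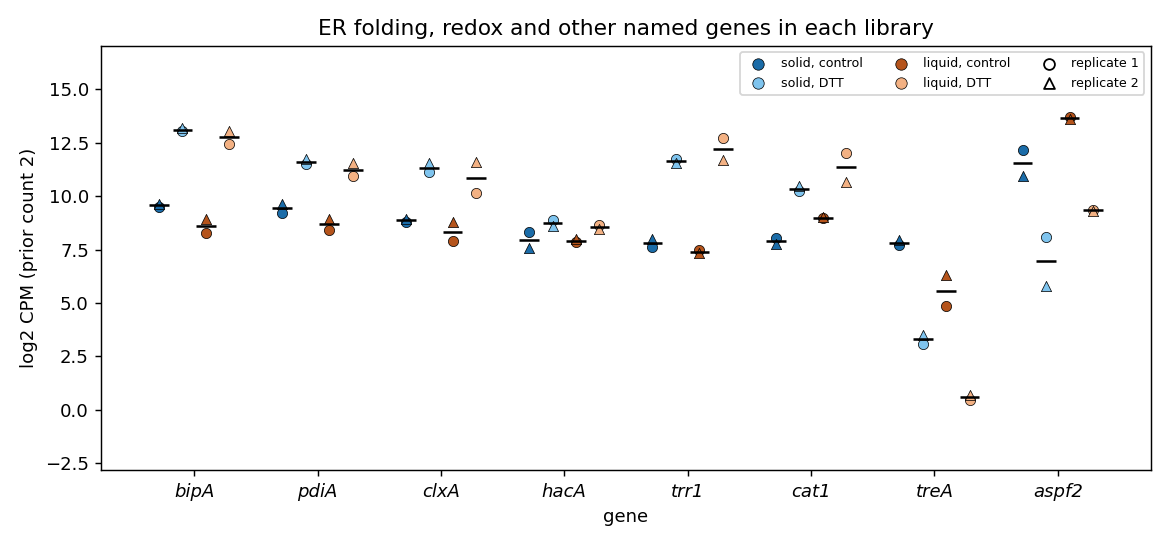
Log2 CPM (prior count 2) of 8 genes in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and black bars for the mean of the 2 libraries. The ER chaperone gene bipA lies higher in every DTT library than in every control library of the same culture (log2 fold change 3.54 in solid and 4.16 in liquid culture), and treA lies lower (-4.55 and -5.38).

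The second comparison asked the same of submerged mycelium. In liquid culture all 3 ER folding genes rose under DTT, bipA from 398 ± 121 to 7090 ± 2060 CPM (n = 2 each; 4.16 ± 0.80), clxA by 2.62 ± 0.73 and pdiA by 2.56 ± 0.66. The redox genes trr1 (4.92 ± 0.77) and cat1 (2.50 ± 0.67) and the mitochondrial chaperone gene hsp78 (AO090038000288) (3.12 ± 0.53) also rose. Transcripts of starch hydrolysis fell, AO090010000746 from 685 ± 400 to 28.8 ± 5.59 CPM and AO090003000321 from 47.8 ± 4.58 to 2.32 ± 1.05 CPM. Ribosomal protein genes fell, among them rps0 (AO090012000801) from 441 ± 138 to 20.8 ± 17.6 CPM. In all, 1885 of 9438 genes changed (841 up, 1044 down) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each moved in the same direction in all 4 pairs of libraries, as a call nearly requires, and by at least 1.22 on the log2 scale.

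All 3 ER folding genes were also called when adjusted over the list alone, and bipA had an adjusted p of 0.0115 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. hacA stood at 0.65 ± 0.48 and was not called. In ER-associated degradation hrdA rose (2.02 ± 0.45), as 1 of 5 genes (2 adjusted over the list alone and 2 with the block; camera adjusted p = 0.234). None of 16 proteasome genes was called (0 adjusted over the list alone), with rpt1 at 0.97 ± 0.45 and pre1 at -0.19 ± 0.44. Of 10 cytosolic and mitochondrial chaperone genes hsp78 rose (1 adjusted over the list alone), and of 9 redox genes 2 rose (2 adjusted over the list alone, 4 with the block). In the signal peptidase list sec11, its 1 gene, was not called over all genes but was when adjusted over the list alone, and with the block.

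Within the same limit of 20 CPM and a symbol, the largest rises were those of aspf34 (AO090003001484) (5.26 ± 1.38), atrF (5.23 ± 0.64), trr1, fgaCat (AO090011000540) (4.83 ± 0.66), rad7 (4.40 ± 0.55), hmgX (AO090003000209) (4.19 ± 1.08), mrsA (AO090003000367) (4.18 ± 0.69) and bipA. Under that limit the largest falls were those of treA (-5.38 ± 0.64), akr1 (AO090023000264) (-4.99 ± 0.75), cdcA (AO090003000789) (-4.75 ± 0.61), pps1 (AO090120000287) (-4.61 ± 0.56), rps0 (-4.42 ± 0.78), aspf2 (-4.33 ± 1.03), rmt2 (AO090011000791) (-4.21 ± 0.60) and gatA (AO090701000206) (-4.15 ± 0.63). In hmgX the treated libraries ranged widely (156 ± 195 CPM).

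3 lists were lower under DTT in liquid culture by camera, again not with an estimated correlation. Ribosomal proteins fell in 4 of 5 genes (5 adjusted over the list alone), among them rps0 and rpl17 (AO090011000367) (-3.10 ± 0.88). The list had a camera adjusted p of 0.00564 and an adjusted p = 0.789 with an estimated correlation. Starch hydrolysis fell in 3 of 5 tested genes (5 adjusted over the list alone, 5 with the block), AO090010000746 by a log2 fold change of -4.57 ± 0.83 and AO090003000321 of -4.31 ± 1.21 (camera adjusted p = 0.0141, adjusted p = 0.734 with an estimated correlation). The list's AO090003001210, AO090023000944 and AO090120000196 had too few reads counted to be tested, or were in no file, so nothing is shown for them. A further gene of this list, AO090003001208, stood at -1.47 ± 0.46 with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0532, and 0.0252 with the block. Ribosome assembly fell in 4 of 28 genes (3 adjusted over the list alone, 8 with the block), such as nop9 (AO090003000665) (-2.19 ± 0.54) and nop58 (AO090012000796) (-2.18 ± 0.50; camera adjusted p = 0.0141, adjusted p = 0.81 with an estimated correlation). This list was not called without liquid DTT replicate 1 (camera adjusted p = 0.155). In sterol synthesis erg8 rose (1.98 ± 0.43) and 7 of 17 genes fell, erg5 (AO090003000954) (-5.49 ± 1.12) and erg2 (AO090003000904) (-2.76 ± 0.60) the most (1 and 7 adjusted over the list alone; camera adjusted p = 0.0542). In cell division 3 of 13 genes fell (4 adjusted over the list alone, 8 with the block), among them psf2 (AO090026000549) of the replication complex GINS (-3.42 ± 0.80) and the kinetochore gene nuf2 (AO090026000704) (-2.24 ± 0.46). The camera adjusted p was 0.0542, and 0.0241 with the block (adjusted p = 0.909 with the block and an estimated correlation).

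In amino acid synthesis 3 of 18 genes fell (3 adjusted over the list alone), including ilv3 (-4.12 ± 0.65) and leu2A (-3.98 ± 0.64). In the list of sulfur assimilation and methionine sC (-3.98 ± 0.58) and mde1 (-2.61 ± 0.51) of 4 genes fell (2 adjusted over the list alone). Of 8 peptidase genes sxa2 (AO090120000232) rose (1.69 ± 0.48) and 3 fell, such as dppIV (-4.00 ± 0.69) and AO090003001036 (-3.58 ± 0.78; 1 and 4 adjusted over the list alone). AO090120000474 of the same list fell as well (-3.10 ± 0.75). In protein glycosylation cwh41 (AO090701000141), the glucosidase I gene (-2.29 ± 0.46), pmi1 (-2.22 ± 0.46) and 1 more of 17 genes fell (4 adjusted over the list alone, 6 with the block). In autophagy and vacuole atg1 rose (2.23 ± 0.46) and the vacuolar mannosidase gene ams1 (AO090005001458) fell (-3.0 ± 0.68) among 10 genes (1 and 1 adjusted over the list alone; 3 rose with the block). In the fungal cell wall list bgt2 (AO090009000117) rose (2.27 ± 0.68) and agm1 (-2.58 ± 0.46) and eng2 (AO090023000083) (-2.28 ± 0.54) fell among 29 genes (0 and 2 adjusted over the list alone; 4 and 3 with the block). Of 12 plant wall hydrolases pgxC (AO090005001400) (-2.96 ± 0.90) and manF (AO090038000444) (-2.12 ± 0.60) fell (0 adjusted over the list alone). The median of this list was -0.36, or 0.09 with the gene that had no reads in 1 condition set at its bound.

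In iron uptake the siderophore transporter gene sit1 (AO090005000471) rose (2.74 ± 0.49), as 1 of 10 genes (1 adjusted over the list alone, 2 with the block; camera adjusted p = 0.213). Of 15 secondary metabolism genes 3 rose (3 adjusted over the list alone; 2 fell with the block), among them fmpC (AO090003001279), at least 88.7-fold higher, and fmaE (AO090010000638), at least 6.71-fold higher, neither with any read in the liquid controls. In the kojic acid cluster AO090113000138 rose (2.06 ± 0.57; 1 of 3 genes, 3 adjusted over the list alone, 2 with the block), with AO090113000137 at 0.95 ± 0.38. AO090113000136 stood at 1.27 ± 0.48, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0902, and 0.0385 with the block. AO090026000003 of the cyclopiazonic acid list fell (-3.11 ± 0.72; 1 of 2 genes, 1 adjusted over the list alone), and mrh4 (AO090011000853) of the mitochondrial ribosome list rose (1.66 ± 0.44; 1 of 3, 1 up and 1 down adjusted over the list alone, 1 and 1 with the block). No gene was called in the lists of vesicle transport (10 genes), glycolysis (4), the tricarboxylic acid cycle (4), the respiratory chain (8), nitrite reductase (1), spore formation (10), aflatoxin homologues (10), hexose transport (1) and oligopeptide transport (4). Adjusted over the list alone, 2 genes of spore formation rose and 2 fell and 0 were called in the others. With the block those 2 and 2 were called too, 1 gene each of vesicle transport, the tricarboxylic acid cycle and the respiratory chain rose, and 1 of glycolysis, 2 of the respiratory chain and 1 aflatoxin homologue fell.

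gpdA (-0.68 ± 0.82), aspf22 (-1.32 ± 0.86), AO090120000080 (-1.43 ± 0.90) and AO090020000588 (-0.70 ± 0.67) were not called in liquid culture. The block raised the count from 1885 to 2984, 1881 of them shared, and only the 4 libraries compared gave 902. The count was 614 (218 up, 396 down) without liquid control replicate 1, 732 (203 up, 529 down) without liquid control replicate 2, 901 (403 up, 498 down) without liquid DTT replicate 1 and 1581 (933 up, 648 down) without liquid DTT replicate 2. Of the 55 calls named here 23, 30, 32 and 36 were then kept. The adjusted p of bipA was 0.0779, 0.059, 0.0219 and 0.0185 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

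The DTT responses of the solid and the liquid cultures overlapped. Among the genes that rose in both were bipA, hrdA, trr1, atrF, rad7, erg8, atg1 and AO090113000138, and among those that fell in both treA, sC, mde1, leu2A, ilv3, dppIV, pmi1, agm1, zrfC and aspf2. In all, 273 genes rose in both, against 40.9 for independent lists (Fisher's exact test across genes, 2-sided, p = 2.17e-179). Likewise 247 fell in both, against 46.3 (p = 2.82e-134, the same exact test). No gene that rose in solid culture fell in liquid culture, and 1 that fell in solid culture rose in liquid culture, against 8 and 8 with the block. The log2 fold changes correlated across genes at Pearson 0.64 and Spearman 0.66. Genes are not independent replicates, so these p-values describe the 2 lists only. The comparisons share no library, but they share each gene's spread, which was estimated from all 8 libraries. A gene of low spread is more easily called in both, so the numbers for independent lists may be too low. With the block 576 genes rose and 624 fell in both. Without 1 library the shared rises and falls were 2 and 2 (without solid control replicate 1), 5 and 9 (solid control replicate 2), 101 and 17 (solid DTT replicate 1), 59 and 9 (solid DTT replicate 2), 154 and 143 (liquid control replicate 1) and 118 and 142 (liquid control replicate 2).

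The third comparison set solid against liquid culture without DTT. Genes named after the gliotoxin cluster of Aspergillus fumigatus were higher on agar, gliP (AO090001000043), the peptide synthetase gene, at 156 ± 4.14 CPM against no read in liquid culture, at least 769-fold, gliI (AO090001000033) at 130 ± 4.53 against 0.308 ± 0.184 CPM and gliM (AO090001000039) at 158 ± 16.2 against 7.73 ± 2.09 CPM (n = 2 each). The glucan synthase gene ags2 (AO090026000523) (6.51 ± 0.72) and AO090020000588 of the cell wall list (322 ± 11.8 against 2.30 ± 0.779 CPM) were higher on agar too. Siderophore genes were higher as well, mirB by a ratio of 369 (95% counting interval 65.8 to 14600, with 1 read in liquid culture) and sidJ by 4.13 ± 0.92. The zinc transporter genes zrfA (AO090003001296) (96.3 ± 37.2 against 5110 ± 413 CPM) and zrfB (AO090005001514) (87.3 ± 19.8 against 738 ± 27.5 CPM) were lower on agar. In all, 367 genes differed, 210 higher and 157 lower on agar, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All had the same direction in the 4 pairs of libraries, as a call nearly requires, and a log2 difference of at least 1.72.

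Besides gliP, gliI, mirB, ags2 and gliM, the largest differences upward among genes with a symbol and at least 20 CPM in the higher condition were those of gliG (AO090001000040) (8.22 ± 0.65), gliC (AO090001000041) (8.12 ± 0.61) and gliJ (AO090001000042) (7.95 ± 1.06). Downward, within the same limit, they were those of zrfA (-5.73 ± 0.84), ergS (AO090011000521) (-5.18 ± 0.93), zrfB (-3.08 ± 0.55), cp1 (AO090701000220) (-2.89 ± 0.54), cp3 (AO090103000332) (-2.54 ± 0.58), nfr1 (AO090038000584) (-2.33 ± 0.50) and cwh41 (-2.32 ± 0.46). The secondary metabolism list was higher on agar in 6 of 15 genes (10 adjusted over the list alone), with a median of 4.35, or 2.10 with its 3 genes that had no reads in 1 condition at their bound. All 6 were gli genes, of which the list holds 7, and 0 of its 8 other genes were called by edgeR's quasi-likelihood test (1 with the block), with fmpA (AO090001000015) at 2.10 ± 0.67, nrps1 (AO090038000390) at 0.57 ± 0.68 and fma-PKS (AO090011000015) at -0.63 ± 0.51. Its camera adjusted p was 6.2e-09, and adjusted p = 0.293 with an estimated correlation. Iron uptake was higher in 3 of 10 genes (6 adjusted over the list alone, 5 with the block), and all 10 values lay above 0 (camera adjusted p = 7.02e-05, adjusted p = 0.734 with an estimated correlation). Ribosome assembly was higher as a list (camera adjusted p = 1.95e-06, adjusted p = 0.789 with an estimated correlation), although none of its 28 genes was called over all genes (9 adjusted over the list alone, 4 with the block). Of its members cbf5 (AO090009000691) stood at 1.81 ± 0.54, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.11, and 0.0458 with the block, and nop58 at 1.64 ± 0.49. Limma's fry called 2 lists between the untreated cultures, against 3 by camera.

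In the fungal cell wall list 3 of 29 genes were higher (3 adjusted over the list alone), among them AO090020000588 (7.14 ± 0.74) and the chitinase gene chi3 (AO090020000231), at least 13.8-fold with no read in liquid culture. The list's median was -0.48 and its mean 0.35. In amino acid synthesis lysB (AO090005001561) (2.80 ± 0.53) and ilv3 (2.76 ± 0.58) of 18 genes were higher (3 adjusted over the list alone; 3 with the block). In starch hydrolysis the alpha-glucosidase gene agdC (AO090005001084) was higher (3.05 ± 0.49; 1 of 5 genes, 1 up and 2 down adjusted over the list alone, 1 and 1 with the block). Its companion AO090003001208 stood at -1.72 ± 0.47, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.081, and 0.0441 with the block. In protein glycosylation och3 (-3.69 ± 0.51) and cwh41 of 17 genes were lower (2 adjusted over the list alone), and among chaperones grpE (AO090026000264) was higher (2.17 ± 0.48; 1 of 10, 1 adjusted over the list alone). No gene was called in the lists of ER folding (3 genes), ER-associated degradation (5), the proteasome (16), signal peptidase (1), vesicle transport (10), redox (9), sulfur assimilation (4), plant wall hydrolases (12), peptidases (8), glycolysis (4), the tricarboxylic acid cycle (4), the respiratory chain (8), ribosomal proteins (5), the mitochondrial ribosome (3), nitrite reductase (1), sterol synthesis (17), autophagy and vacuole (10), spore formation (10), kojic acid (3), cyclopiazonic acid (2), aflatoxin homologues (10), hexose transport (1), oligopeptide transport (4) and cell division (13). Adjusted over the list alone, 2 plant wall hydrolases and 2 genes of spore formation were higher, as was 1 each of the respiratory chain and the mitochondrial ribosome. On the same terms 2 plant wall hydrolases, 1 gene of autophagy and 1 of spore formation were lower. With the block 1 respiratory gene, 1 peptidase gene and 1 gene of spore formation were higher, and 2 plant wall hydrolases, 1 peptidase gene and 1 gene of autophagy were lower.

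The ER genes bipA (0.94 ± 0.71), pdiA (0.73 ± 0.62) and hacA (0.08 ± 0.48) were not called between the untreated cultures. Neither were gpdA (-0.17 ± 0.81), aspf22 (0.18 ± 0.84), AO090120000080 (0.74 ± 0.89), cat1 (-1.10 ± 0.64), AO090010000746 (1.13 ± 0.72), AO090003000321 (1.27 ± 1.04), AO090003001036 (-1.48 ± 0.71) and the kojic acid genes AO090113000136 (1.19 ± 0.47), AO090113000137 (-0.49 ± 0.38) and AO090113000138 (-1.57 ± 0.60). AO090120000474 stood at -2.39 ± 0.72, with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.109, and 0.032 with the block. The block raised the count from 367 to 771, which held all 367. Leaving out 1 library gave 91 genes (79 higher, 12 lower) without solid control replicate 1, 67 (64 higher, 3 lower) without solid control replicate 2, 116 (80 higher, 36 lower) without liquid control replicate 1, 184 (71 higher, 113 lower) without liquid control replicate 2 and 246 (141 higher, 105 lower) without solid DTT replicate 2. Of the 23 calls named here 11, 8, 11, 11 and 17 were then kept.

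**Figure D3:**
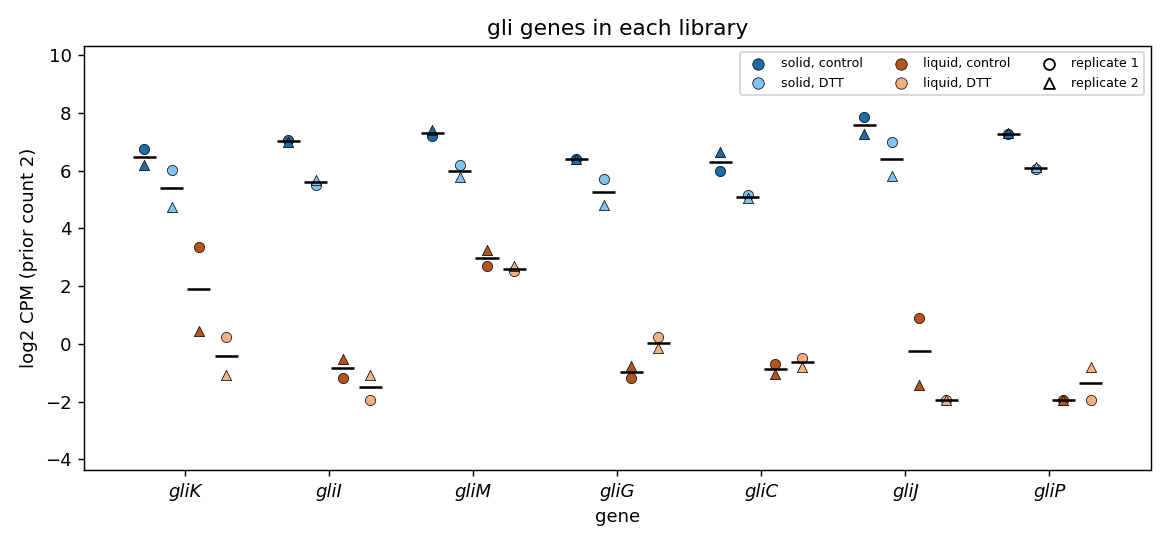
Log2 CPM (prior count 2) of the gli genes of the secondary metabolism list in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and black bars for the mean of the 2 libraries. The gene gliP lies at 156 ± 4.14 CPM in the untreated solid libraries and at 0 reads in the untreated liquid libraries.

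The fourth comparison set solid against liquid culture under DTT. The gli genes were again higher on agar, gliJ at 91.7 ± 51.3 CPM against no read in liquid culture, at least 376-fold, and gliP by a ratio of 317 (95% counting interval 108 to 1540, with 3 reads in liquid culture). Of the starch hydrolysis list 2 of 5 genes were higher on agar, AO090010000746 at 1240 ± 845 CPM against 28.8 ± 5.59 in liquid culture and agdC at 58.7 ± 16.7 against 5.41 ± 1.91 CPM (n = 2 each). The spore formation regulator gene brlA (AO090005001041) (2.85 ± 0.63) and the ribosomal protein gene rps0 (3.67 ± 0.76) were higher on agar. The siderophore transporter gene sit1 was lower, at 34.4 ± 5.64 against 362 ± 10.9 CPM. In all, 278 genes differed, 222 higher and 56 lower on agar, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each differed in the same direction in the 4 pairs of libraries, as a call nearly requires, and by at least 1.74 on the log2 scale.

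Within that limit of 20 CPM and a symbol, the largest differences upward also included gliI, with a ratio of 341 (95% counting interval 94.2 to 2820, with 2 reads in liquid culture), gliK (AO090001000030) (6.54 ± 1.19), gliC (6.47 ± 0.58), gliG (5.71 ± 0.58), gatA (5.52 ± 0.66) and ags2 (4.83 ± 0.66). Only 4 genes met this limit downward, sit1 (-3.40 ± 0.50), ish1 (AO090003000594) (-3.31 ± 0.59), kat1 (AO090012000715) (-2.19 ± 0.44) and nar1 (AO090003001020) (-2.17 ± 0.44). The secondary metabolism list was higher on agar in 7 of 15 genes and lower in fmpC, by a ratio of 104 (95% counting interval 35.1 to 507, with 3 reads in the solid libraries). The 7 were its 7 gli genes, and of the 8 others 0 were called higher by edgeR's quasi-likelihood test (1 with the block), with fmpA at 2.89 ± 0.69, nrps1 at -1.89 ± 0.70 and fma-PKS at -1.10 ± 0.51. Adjusted over the list alone 10 were higher and 2 lower. The list had a camera adjusted p of 0.00064 and an adjusted p = 0.734 with an estimated correlation. Its median was 2.89, also with the gene without reads in 1 condition at its bound. The spore marker brlA was higher beside these genes, as 1 of 10 in its list (3 adjusted over the list alone, and 2 up and 1 down with the block; camera adjusted p = 0.962). Ribosome assembly was higher as a list, with nop58 (2.59 ± 0.51) called among 28 genes (5 adjusted over the list alone, 5 with the block; camera adjusted p = 2.69e-05, adjusted p = 0.795 with an estimated correlation). Ribosomal proteins were higher too, with rps0 called of 5 genes (4 adjusted over the list alone, 2 with the block; camera adjusted p = 0.00363, adjusted p = 0.789 with an estimated correlation). Limma's fry called 1 list in this comparison, against 3 by camera.

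In starch hydrolysis AO090010000746 (5.43 ± 0.86) and agdC (3.42 ± 0.51) were higher among 5 genes (3 adjusted over the list alone; camera adjusted p = 0.159). In the fungal cell wall list 3 of 29 genes were higher (3 adjusted over the list alone), among them AO090020000588 (7.28 ± 0.75) and chi3, at least 14-fold with no read in liquid culture, and 2 were lower with the block. The branched-chain gene ilv3 (3.52 ± 0.63) was higher as 1 of 18 genes of amino acid synthesis (2 adjusted over the list alone, 2 with the block), and AO090026000003 of the cyclopiazonic acid list (4.41 ± 0.76) as 1 of 2 (1 adjusted over the list alone). In iron uptake sit1 was lower as 1 of 10 genes (2 adjusted over the list alone, 2 with the block; camera adjusted p = 0.0883). No gene was called in the lists of ER folding, ER-associated degradation, the proteasome, signal peptidase, protein glycosylation, vesicle transport, chaperones, redox, sulfur assimilation, plant wall hydrolases, peptidases, glycolysis, the tricarboxylic acid cycle, the respiratory chain, the mitochondrial ribosome, nitrite reductase, sterol synthesis, autophagy, kojic acid, aflatoxin homologues, hexose and oligopeptide transport and cell division. Adjusted over the list alone, 3 plant wall hydrolases and 2 aflatoxin homologues were higher, as was 1 gene each of signal peptidase, chaperones, sulfur assimilation, the mitochondrial ribosome, sterols and autophagy. On the same terms 2 redox genes and 1 chaperone gene were lower. With the block 2 plant wall hydrolases, 2 peptidase genes and 2 aflatoxin homologues were higher, as was 1 gene each of glycosylation, signal peptidase, chaperones, the respiratory chain, the mitochondrial ribosome, sterols and autophagy. Also with the block 1 gene each of chaperones, redox, sterols and autophagy was lower.

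Under DTT bipA (0.32 ± 0.70), pdiA (0.34 ± 0.62) and hacA (0.19 ± 0.48) were not called between the cultures. Neither were gpdA (-0.06 ± 0.81, but 0.02 with upper-quartile scaling), aspf22 (0.58 ± 0.85), AO090120000080 (1.23 ± 0.89), cat1 (-1.14 ± 0.64), AO090003000321 (3.34 ± 1.17), AO090003001208 (-1.01 ± 0.46), AO090003001036 (-0.07 ± 0.73), AO090120000474 (-0.75 ± 0.76) and the kojic acid genes AO090113000137 (0.18 ± 0.38) and AO090113000138 (-0.82 ± 0.55). The third kojic acid gene, AO090113000136, was at 17.6 CPM in both. The block raised the count from 278 to 992 (648 higher, 344 lower), which held all 278, and only the 4 libraries compared gave 95. Leaving out 1 library gave 92 (solid control replicate 1), 81 (solid control replicate 2), 87 (solid DTT replicate 1), 60 (solid DTT replicate 2) and 72 genes (liquid DTT replicate 1). Of the 22 calls named here 13, 11, 11, 9 and 12 were then kept. Without liquid DTT replicate 2 the count was 322 (106 higher, 216 lower).

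The last comparison tested whether the DTT response itself differed between the cultures. The iron uptake list responded lower in solid than in liquid culture, with a median difference of -3.35 on the log2 scale and all 10 genes below 0 (camera adjusted p = 6.2e-09, adjusted p = 0.734 with an estimated correlation). Of these genes mirB (0 to 1.13 CPM) and sidH (AO090103000168) (0 to 1.36 CPM) lay near the floor in the liquid libraries, so their DTT effect there could hardly be measured. Secondary metabolism also lay lower, with a median difference of -1.65, or -0.88 with its 4 genes that had no reads in some condition set at the floor of 3 reads (camera adjusted p = 0.0141, adjusted p = 0.734 with an estimated correlation). Further members of this list not set at the floor lay near it in the liquid libraries, gliI at 0 to 0.438, gliG at 0.178 to 0.903 and gliC at 0.219 to 0.452 CPM. Their DTT effect in liquid culture, and so its difference, could hardly be measured. No single gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0799, sit1). The ER folding genes bipA (-0.62 ± 1.0) and pdiA (-0.39 ± 0.88) and the regulator hacA (0.12 ± 0.68) were among those not called. At an unadjusted p under 0.05 there were 1003 genes, against 204 called by DESeq2, 23 with the block, 26 without the filter on low counts and 0 by edgeR's test against a fold change of 1.5.

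In the iron uptake list 0 of 10 genes were called over all genes, 6 when adjusted over the list alone and 1 with the block, and sit2 (AO090005000166) stood at -3.64 ± 1.20 and mirC (AO090001000692) at -1.25 ± 0.73. In secondary metabolism 0 of 15 genes were called (1 adjusted over the list alone, 1 with the block), with nrps1 at -2.46 ± 0.98, while gliJ, which had no read in the liquid DTT libraries, is given no value. In the list test the call was kept without solid control replicate 2 (0.0206). Without any other single library its camera adjusted p was over 0.05: 0.214 without solid control replicate 1, 0.0608 and 0.214 without liquid control replicates 1 and 2, 0.121 and 0.0618 without solid DTT replicates 1 and 2, and 0.0865 and 0.124 without liquid DTT replicates 1 and 2. In the other 30 lists 0 genes were called over all genes. When adjusted over the list alone, 2 genes of glycosylation, 1 of starch hydrolysis and 1 of cyclopiazonic acid lay higher, as did 1 gene of glycosylation with the block.

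Of the other genes followed throughout, AO090010000746 differed most, at 4.30 ± 1.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.225). AO090003000321 stood at 2.07 ± 1.51, AO090003001208 at 0.71 ± 0.64, AO090003001036 at 1.41 ± 1.01, AO090120000474 at 1.64 ± 1.03, AO090113000136 at -1.19 ± 0.66, AO090113000137 at 0.68 ± 0.54 and AO090113000138 at 0.76 ± 0.80. AO090020000588 (0.14 ± 0.83), gpdA (0.11 ± 1.15), AO090120000080 (0.49 ± 1.25), aspf22 (0.40 ± 1.19) and cat1 (-0.05 ± 0.90, but 0.04 with upper-quartile scaling) lay near 0 relative to their errors. Of the 23 genes called with the block, those with a symbol were sit1 (-6.34), fmpC, eaf1 (AO090023000819) (3.28) and och3 (4.30), singled out here after their values were seen. Their adjusted p were 0.0269, 0.0396, 0.0431 and 0.0431 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, insert size as a block). In the simulated data the number of changed genes was set, and it need not match this comparison. There the test recovered 2 of 100 genes with a 4-fold and 0 of 100 with a 2-fold difference. Without liquid DTT replicate 2 it called 7 genes.

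**Figure D4:**
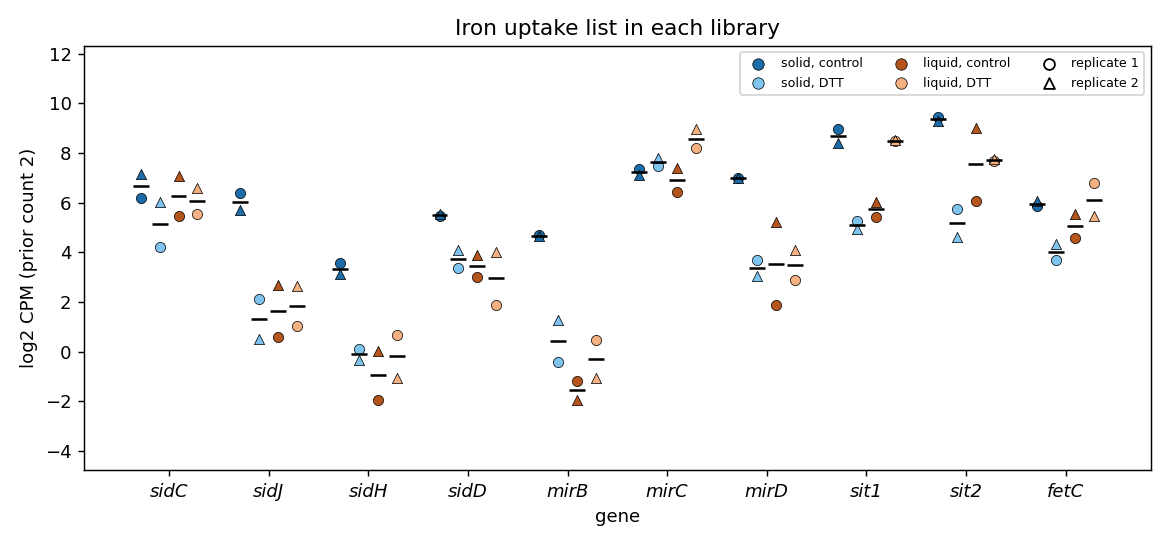
Log2 CPM (prior count 2) of the measured genes of the iron uptake list in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and black bars for the mean of the 2 libraries. The difference of the DTT effects, solid minus liquid, lay below 0 in all 10 tested genes, with a median of -3.35, but no single gene was called without the block. The gene mirB fell in solid culture by a log2 fold change of -4.16.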

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

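The tests of covered length, insert sizes and scaling were chosen only after the results they bear on had been seen, and the test of shared coverage was chosen before.

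Outside the tested counts, 71 protein-coding genes were listed with coverage above 0 but with 0 reads in every library that lists them. Of these, 36 had enough different coverage values to be compared, and 21 shared their fractions to the last deposited digit in every library with another gene, against 0 of 10652 genes with reads and enough values. This is what reads from identical copies, counted for no copy, could give, although the threshold of 20 set beforehand was only narrowly passed. Too few reads on the gene remains open for part of the genes. The covered length in the best covered library had a median of 232 bp with quartiles of 87 and 981 bp, against a read length of 44 bp. It was computed for 67 genes with a recovered length of at least 100 bp. A recovered length may be only a divisor of the true one, so covered lengths may be understated. No biological explanation was tested, and counts of multi-copy genes, such as the starch hydrolysis gene AO090120000196 with 0 reads at 98.3% to 100% coverage, are uncertain.

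The DTT response of the iron uptake list differed between the cultures, by a median of -3.35 (camera). The median was -4.55 among replicate 1 and -2.58 among replicate 2 libraries, with 10 of 10 genes below 0 in both. The difference therefore did not come from 1 insert size alone. Each condition held both insert sizes, so a shift shared by all conditions cancels here. Being parts of the same values, the 2 medians are no separate test. In the liquid libraries mirB (0 to 1.13 CPM) and sidH (0 to 1.36 CPM) lay near the floor, so their DTT effect there could hardly be measured. Scaling between libraries does not account for the list's difference, as no other scaling moved the median of all genes by more than 0.08. A response of siderophore genes that depends on the culture may underlie the difference, a hypothesis found and tested on the same data. It stays open beside the higher level of the list on agar before treatment (median 2.31) and the transfer of treated solid cultures to filter paper, and camera's adjusted p was 0.734 with an estimated correlation.

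The DTT response of the secondary metabolism list also differed between the cultures by the same test, with a median of -1.65 (-0.88 with its 4 genes that had no reads in some condition at the floor of 3 reads) and an adjusted p = 0.734 with an estimated correlation. For gliI, gliG and gliC, at 0.903 CPM or less in every liquid library, the DTT effect in liquid culture could hardly be measured. The list's difference therefore rests in part on genes near the floor. The call of this list by camera was not kept in most fits without 1 library. With the insert size as a block, 23 genes differed in their DTT response between the cultures, against 0 without it by edgeR's quasi-likelihood test, 1003 at an unadjusted p under 0.05 and 204 by DESeq2.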

How the results depend on the processing

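The setting without rRNA and tRNA genes and the list tests and overlaps without single libraries were chosen after seeing the data, and the other tests were planned. Alternatives for normalized units were not run, since the files hold counts. Of 134 called gene results named in the text, 100 missed the threshold in at least 1 setting and 0 changed sign. Since each had 1 direction in all 4 pairs of libraries, the loss of a library could hardly turn it, so this count of 0 says little about stability. With the replicate block all 134 were kept. Beyond those printed with the results, the block changed no call of a named gene or list. Of 82 named results that were not called, 23 changed sign in some setting. With 2 libraries per condition, leaving out 1 leaves 3 residual degrees of freedom for the spread. On simulated data with all libraries edgeR's test recovered at most 11 of 100 genes changed 4-fold. Fewer genes changed there than were called here, except for the difference of effects, so this is not the recovery in the real data. RLE and upper-quartile scaling and the loss of rRNA and tRNA genes kept each count within 1.5 times, and the largest shift of the median of all genes was 0.10 (DTT in solid culture, upper-quartile scaling).

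At a threshold of 0.01 there were 49 calls (DTT, solid), 410 (DTT, liquid), 85 (cultures, control) and 34 (cultures, DTT). Without the filter on low counts there were 569 (cultures, control), 610 (cultures, DTT) and 26 (difference of DTT effects). With the replicate block there were 1897, 2984, 771, 992 and 23 in the order of the report, and 1489, 642, 889 and 14 on genes of 700 bp or more for all but DTT in liquid culture. Only the 4 libraries compared gave 902 (DTT, liquid) and 95 (cultures, DTT), and the test against a fold change of 1.5 gave 553 (DTT, solid) and 177 (cultures, DTT). DESeq2 gave 1628 (DTT, solid), 872 (cultures, control), 1088 (cultures, DTT) and 204 (difference). On simulated data it made false calls where edgeR made 0, but genes of like level shared 1 spread there, so this may not hold for the real data. Stricter thresholds lower these counts by construction, and for the rest the cause was not tested.

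Of the lists, camera with an estimated correlation called 0 in all 5 comparisons (against 5, 3, 3, 3 and 2), and fry called 5, 6, 2, 1 and 3 in the same order. The overlap of the DTT calls was 576 (rose) and 624 (fell) with the replicate block. Leaving out 1 library at a time gave 6 to 1207 calls (DTT, solid), 614 to 1581 (DTT, liquid), 67 to 437 (cultures, control), 60 to 322 (cultures, DTT) and 0 to 7 (difference). It gave 1 to 6, 3 to 5, 3 to 6, 3 to 4 and 1 to 4 called lists in the same order, and overlaps of 2 to 351 (rose) and 2 to 237 (fell).

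Adjusted p of results that were called with the replicate block but not without it ranged over the alternatives, library losses included, from 7.6e-05 to 0.265 (pdiA) and 0.000237 to 0.284 (cat1) and 0.000364 to 0.278 (clxA) for DTT in solid culture. For DTT in liquid culture they ranged from 0.0236 to 0.195 (AO090003001208) and 0.0346 to 0.381 (AO090113000136). Between the untreated cultures they ranged from 0.0202 to 0.482 (cbf5), 0.0177 to 0.464 (AO090003001208) and 0.0309 to 0.515 (AO090120000474), and under DTT from 2.85e-07 to 0.285 (zrfC). For the difference of DTT effects they ranged from 1.42e-16 to 0.291 (sit1), 1.52e-05 to 0.291 (fmpC), 0.0431 to 0.614 (eaf1) and 0.000129 to 0.372 (och3). The lowest for pdiA, cat1, clxA, cbf5, zrfC, sit1, fmpC and och3 came from DESeq2. For bipA the range was 2.36e-12 to 0.194 (solid) and 2.4e-17 to 0.0779 (liquid).

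Signs that turned all belonged to results not called. They were hsp90 under DTT in solid culture (-0.01 without the filter and with the block on genes of 700 bp or more), gpdA between cultures under DTT (0.02, upper-quartile scaling) and AO090113000136 between cultures under DTT. The last was -0.03 with RLE, -0.02 with the filter of 50 reads, without rRNA and tRNA genes and with DESeq2, -0.01 with the replicate block and -0.04 on genes of 700 bp or more. The difference of DTT effects for cat1 was 0.04 with upper-quartile scaling, 0.06 with the block and 0.02 on genes of 700 bp or more. Without 1 library, log2 values for DTT in solid culture ranged from -1.23 to 0.37 (AO090010000746), -1.42 to 0.04 (gpdA), -1.04 to 0.35 (hsp70) and -0.48 to 0.57 (hsp90). In liquid culture they ranged from -1.60 to 0.04 (AO090020000588) and -0.41 to 0.07 (pre1). Between the untreated cultures they ranged from -0.69 to 2.08 (AO090003000321), -2.30 to 0.29 (AO090003001036), -0.02 to 1.25 (AO090120000080), -0.15 to 0.56 (aspf22) and -0.33 to 0.41 (hacA). Under DTT they ranged from -0.34 to 0.16 (AO090003001036), -0.14 to 0.14 (AO090113000136), -0.54 to 1.21 (aspf22) and -0.89 to 0.48 (gpdA). The difference of DTT effects ranged from -0.42 to 4.04 (AO090003000321), -0.36 to 2.22 (AO090003001036), -0.56 to 1.03 (AO090020000588), -0.13 to 1.23 (AO090120000080), -0.71 to 1.05 (aspf22), -0.57 to 0.77 (cat1), -0.72 to 0.68 (gpdA) and -0.22 to 0.54 (hacA). The cause was not tested.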

Other observations

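The tests of the zinc list, including those without single libraries, and of the runs of neighbouring genes were chosen after the values had been seen, while the tests of single genes were planned.

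The zinc genes aspf2 and zrfC fell under DTT in both cultures, and zrfA and zrfB were lower on agar without DTT. The gene aspf2 stood at 13000 ± 757 CPM in untreated liquid culture, 3280 ± 1860 on agar, 644 ± 15.2 in liquid culture with DTT and 166 ± 156 on agar with DTT (SD, n = 2 each). In the same order zrfC, which carries the next locus tag, stood at 8570 ± 430, 1310 ± 825, 750 ± 271 and 55.8 ± 27.3 CPM. Of the 5 zinc genes (zrfA, zrfB, zrfC, zrfD and aspf2), 2 were lower on agar without DTT (4 adjusted over the list alone, 4 with the block), and all 5 lay below 0. Camera, Benjamini-Hochberg adjusted over this list's 5 tests, gave an adjusted p of 4.2e-06, and adjusted p = 0.241 with an estimated correlation. Under DTT 0 of the 5 were called between the cultures (3 adjusted over the list alone, 3 with the block; camera adjusted p = 0.000158, adjusted p = 0.241 with an estimated correlation). Of these, zrfC stood at -3.75 ± 0.85 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0527, and 0.0222 with the block) and aspf2 at -1.96 ± 0.93. DTT lowered 2 of the 5, aspf2 and zrfC, in liquid culture (2 adjusted over the list alone, 3 with the block). The list's camera adjusted p there was 0.0235, adjusted p = 0.424 with an estimated correlation, and 0.116 without liquid DTT replicate 2. In solid culture the same 2 fell (2 adjusted over the list alone; camera adjusted p = 0.492). In solid culture the list's median was 0.41 and its mean -1.19. The difference of the DTT effects was not called (camera adjusted p = 0.151), but was without solid control replicate 1 (0.045) and solid DTT replicate 2 (0.0131). Without 1 library some of these gene calls ended (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In solid culture the DTT calls ended without solid control replicates 1 and 2 (zrfC 0.0905 and 0.0821, aspf2 0.131 and 0.127) and solid DTT replicates 1 and 2 (zrfC 0.0814 and 0.142, aspf2 0.0638 and 0.181), and for aspf2 without liquid control replicate 2 (0.0503). In liquid culture they ended without liquid control replicates 1 and 2 (zrfC 0.0608 and 0.0597, aspf2 0.0565 and 0.0567) and liquid DTT replicates 1 and 2 (zrfC 0.0999 and 0.0548, aspf2 0.0927 and 0.0788). Between the untreated cultures they ended without solid control replicates 1 and 2 (zrfA 0.0707 and 0.13, zrfB 0.113 and 0.202) and, for zrfB, without liquid control replicates 1 and 2 (0.0647 and 0.0589).

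Genes higher on agar without DTT lay next to each other in the order of assembly ASM18445v3. The longest run of neighbouring called genes held 17, from AO090001000032 to AO090001000048, with gliI, gliM, gliG, gliC, gliJ and gliP among them, against at most 4 in 1000 shuffles of the 210 calls. Reads of 1 gene counted for its neighbours stay open: the log2 fold changes of the 17 had an SD of 3.10 against a median SE of 0.84, but each gene's own low level in liquid culture also sets its fold change, so this decides nothing. The longest run was 9 without either solid control library or either liquid control library, with 14 (each solid control) and 15 (each liquid control) of the 17 still called. The run may reflect shared control of a gene cluster, a hypothesis found on these data that was not tested.

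Further runs higher on agar held 9 genes (AO090026000577 to AO090026000586) and 8 genes (AO090701000860 to AO090701000867), and 5 neighbours of the latter, AO090701000861 to AO090701000865, fell under DTT in solid culture with log2 fold changes from -5.0 to -3.29.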
